A study of Escherichia coli K-12 with 2 samples.

How the data were processed

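RNAs that co-purified with the small regulatory RNA GcvB in Escherichia coli K-12 were sequenced by MAPS, in which an sRNA carrying the MS2 hairpin tag is captured on a column through the MS2 coat protein and the RNAs bound to it are eluted and sequenced. Per the labels, the strain was MG1655 rne131 with gcvB deleted, where rne131 is an allele of the RNase E gene, and the sRNA was supplied by a 10 min induction with 0.1% arabinose. Per the labels' protocols, lysates were passed over amylose resin loaded with 200 pmol of an MS2 coat protein fusion, the column was washed with 8 mL of buffer, and RNA was eluted with 15 mM maltose. There were 2 libraries, 1 from cells with MS2-tagged GcvB and 1 from control cells with untagged GcvB. The labels name exponential phase (OD600 of 0.5) and stationary phase (OD600 of 1) for each sample. The table holds 1 count column per sample, so the phases could not be compared, and whether cells of both phases were pooled is not given in the sources used here.

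The authors deposited a single table with whole-number read counts for 4337 gene rows and 3037 rows for regions between 2 named genes. Reads were aligned with Bowtie, per the submitters' processing notes. The version, genome build, counting tool, annotation and use of strand are not given in the sources used here, so reads from a gene and from an antisense transcript could not be told apart, and reads in near-identical copies (the rRNA and some tRNA genes) are uncertain between copies. No row held 0 and the smallest value in both columns was 1. A listed 1 can therefore stand for 0 reads, and it was the value of 785 rows in the MS2-GcvB library and 4093 rows in the control library. The deposited normalized columns equal the count divided by 1 number per library, 3917344 for MS2-GcvB and 3992940 for the control. The listed counts made up only 13.8% and 9.71% of these numbers, and what else they include is not given in the sources used here. The deposited ratio of each row equalled the quotient of the normalized columns within 0.0501 in 100% of rows.

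Depth was taken as the sum of the listed counts, 541725 in the MS2-GcvB library and 387584 in the control. A single count was worth 1.85 and 2.58 CPM (the count over the listed total, times 1000000), and the median row held 7 and 1 counts. Counts were scaled to CPM of the listed total. The log2 ratio of MS2-GcvB over control was computed with a pseudocount of 1 CPM, which understates the change of low genes. Rows with at least 10 counts in the higher library were kept, 2414 gene rows and 865 regions. A row was called higher or lower at a 4-fold difference on that scale. Ratios printed without a log are plain quotients of CPM, with an exact 95% interval from the conditional binomial distribution of the 2 counts. A listed 1 entered these as 1 count, so the intervals of such rows hold only if it was 1 read. Shares have exact Clopper-Pearson 95% intervals. All intervals cover counting error only, since the reads carry no molecular identifiers and each group has 1 library. No p-values were computed and no count model such as a negative binomial fit was used, because the design has no replicate check.

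The 17 gene lists were written before the data were examined. The list of reported GcvB targets was drawn from general knowledge of work on Escherichia coli and Salmonella, and some members may first have been reported from these libraries, so it is not wholly independent evidence. The median log2 ratio of each list was set against the medians of 10000 random lists of the same size, matched on mean level in 20 bins, and its percentile describes these libraries. A list was said to stand apart at or above percentile 97.5 or at or below percentile 2.5. The random lists draw single genes, while several lists hold genes of shared operons or near-identical copies. Ratios of such genes can move together, so the percentiles may overstate how far these lists stand apart. Genes named in the text were chosen by a rule fixed before the data were examined: gcvB, the 12 highest and 4 lowest gene rows kept, up to 10 reported targets past 4-fold by size, the 2 reported targets with the lowest ratios, and the highest member of each other list. Other genes, all regions and the values along operons were chosen after their values were seen, except as members of the fixed lists.

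Gene names were matched to the RefSeq table of assembly ASM584v2. Of 4337 gene rows, 3935 matched a symbol, 220 matched a synonym only and 182 matched neither. The names of 165 rows end in the mark of a truncated gene. The table was used for names and gene order only. No coordinates are given because the build of the counts is not stated, and the planned search for sequences complementary to GcvB near start codons was not analysed here for lack of a genome sequence.

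The procedure was tested on 2 sets of simulated data drawn from the mean of both libraries, each with 200 genes raised by known folds. The first set raised genes of any level from 10 expected counts up, abundant ones included, which took a larger share of the total and lowered the log2 ratio of unchanged genes by 1.50. Of 50 genes per fold, 0 raised 3-fold, 2 raised 8-fold, 47 raised 16-fold and 50 raised 32-fold were called, and none of 1363 unchanged genes, among 1563 tested. Scaling to the listed total thus missed most 8-fold changes when abundant RNAs rose too. The second set was made after this result was seen and raised only genes of 10 to 200 expected counts. Here 6 genes raised 3-fold, 47 raised 8-fold and 50 each raised 16- and 32-fold were called, and 4 of 1600 unchanged genes, among 1800 tested. That recovery holds only for such a change of moderately abundant genes. Both sets raised only genes of at least 10 expected counts at the depth of the control. In the data, 543 gene rows kept have a control value listed as 1, and recovery of such genes was not tested. Neither set shifted unchanged genes upward, while the median log2 ratio in the data was 2.02, so the few false calls do not carry over. The alternatives tried were the scaling between libraries, the pseudocount, the minimum count, the fold threshold, the matching of the random lists, the treatment of the listed 1, the denominator of shares and the members of the target list. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.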

Results

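To identify the RNAs that associate with GcvB, an Hfq-dependent sRNA known to repress mRNAs of amino acid and peptide transport, RNA retained with MS2-tagged GcvB was compared with RNA retained from cells expressing untagged GcvB. Each group had 1 library, with 541725 listed counts for MS2-GcvB and 387584 for the control, so no difference below has a replicate check and every interval covers counting error only.

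The bait RNA was the most abundant row of the MS2-GcvB library. gcvB held 85195 counts, or 157266 CPM (exact Poisson 95% interval 156212 to 158326), against 406 counts, or 1048 CPM (948 to 1155), in the control. The ratio was 150 (136 to 166). In the authors' deposited table, which uses other library totals, the ratio of gcvB is 213.9. The log2 ratio was 7.23, and it was 5.95 when scaled by the median ratio of genes above 1 in both libraries and 5.21 relative to the median gene. The region between gcvA and gcvB had 1415 counts against a listed 1, a ratio of 1012 (181 to 40015). The gcvA gene itself had 13 and 9 counts, a ratio of 1.03 (0.409 to 2.74).

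rRNA made up 40.3% (40.2 to 40.5) of the listed counts in the MS2-GcvB library and 62.8% (62.7 to 63.0) in the control. The difference lay in 23S rRNA, at 18.3% and 41.9%, while 16S rRNA was at 22.0% and 20.7%. The gcvB row took 15.7% (15.6 to 15.8) and 0.105% (0.0948 to 0.115). The tff, rpsB and tsf rows together took 0.179% (0.168 to 0.191) with the tagged bait and 11.0% (10.9 to 11.1) in the control. tRNA genes were at 0.139% (0.130 to 0.150) and 0.0784% (0.0699 to 0.0878). The other sRNA and noncoding RNA genes, with Hfq-dependent sRNAs and without tff, were at 0.175% in each library. Outside rRNA, tRNA and gcvB, 50% of the counts lay in 193 rows of the MS2-GcvB library and in 19 rows of the control.

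Just over 50% of the gene rows kept were at least 4-fold higher in the MS2-GcvB library on the CPM scale. Of 2414 gene rows kept, 1221 were at least 4-fold higher and 114 at least 4-fold lower, and the median log2 ratio over all of them was 2.02. In 543 of the rows kept the control value was the listed minimum of 1. Such a row was kept only with at least 10 MS2-GcvB counts, so the filter alone made it at least 4-fold higher. The counts of higher genes in the lists below share this limit. Without the filter, 1397 of 4337 gene rows were at least 4-fold higher. Relative to the median gene, 185 rows were at least 4-fold higher and 380 at least 4-fold lower. The count of higher genes thus depended on the scaling, and gene groups are set against random lists from the same libraries.

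**Figure D1:**
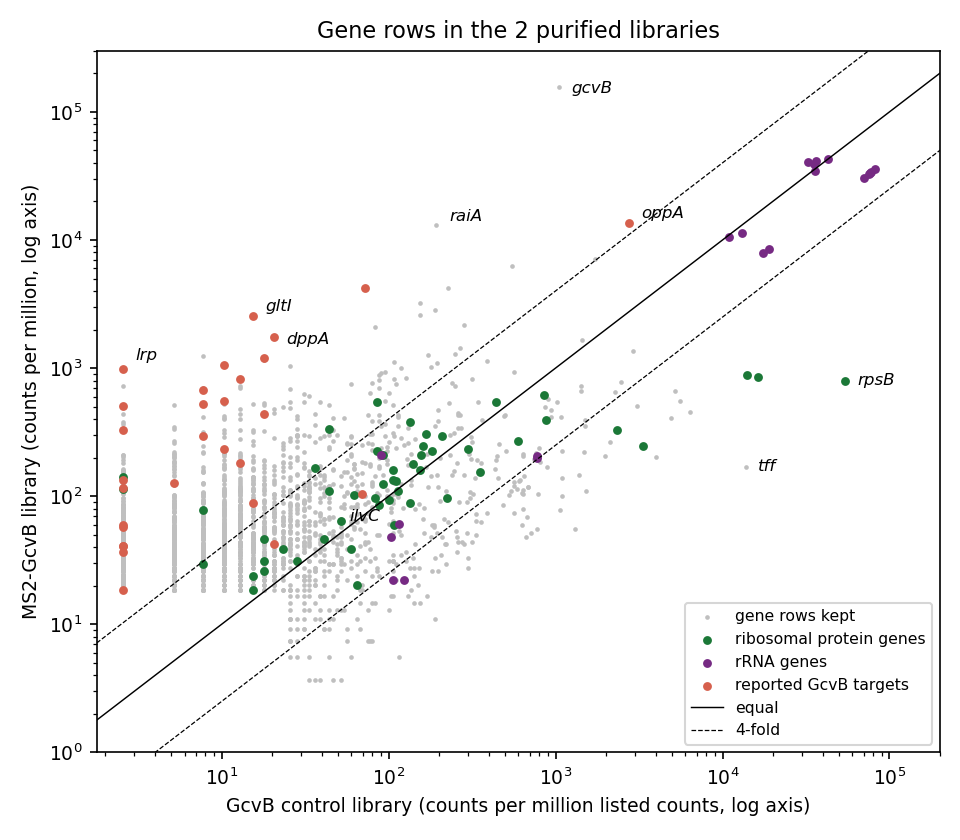
CPM of each gene row kept (at least 10 counts in the higher library), control on the x axis and MS2-GcvB on the y axis, both logarithmic. Each point is a gene in 1 library per group, the solid line marks equal values and the dashed lines 4-fold differences. gcvB (157266 against 1048 CPM) and most reported GcvB targets lie above the upper dashed line, rpsB and tff lie below the lower one, and points at the left edge have a listed control value of 1.

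lrp, the leucine-responsive global regulator, had the highest log2 ratio, with 537 counts against a listed 1, a ratio of 384 (68.7 to 15203). It was followed by ivbL, the leader peptide gene of the ilvB operon, with 392 against 1 (ratio 280). gltI, the periplasmic glutamate and aspartate binding protein, had 1391 against 6 (166, 76.0 to 453). cysJ, a subunit of sulfite reductase, had 671 against 3 (160, 54.5 to 778). cycA, a permease for glycine and D-amino acids, had 274 against 1 (196, 34.9 to 7771). ilvB, of acetolactate synthase, had 238 against 1 (170, 30.3 to 6754), and panD, aspartate decarboxylase of pantothenate synthesis, had 204 against 1 (146, 25.9 to 5793). The remaining members of the 12 highest rows were gcvB, yqiC with 198 against 1, gdhA (glutamate dehydrogenase) with 577 against 4, ilvE (branched-chain aminotransferase) with 178 against 1, and yacL with 280 against 2. Among these 12 rows, 5 were reported GcvB targets, and 11 of the 30 highest rows were. Apart from gcvB, these genes had 6 or fewer control counts, which makes their counting intervals wide, and a listed 1 can stand for 0 reads. Their order depended on how low counts were treated. With a listed 1 raised to 3 counts, the log2 ratio of lrp was 6.85, below gltI at 7.31. With a pseudocount of 10 these were 6.31 and 6.66.

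Reported GcvB targets were far above the other genes. Of 31 listed genes, 29 had enough counts, 27 of these were at least 4-fold higher and none was 4-fold lower. Their median log2 ratio was 5.03, which was 3.01 above the median gene, and it lay at percentile 100 of matched random lists, whose middle 95% spanned 0.30 to 2.62. Of the 29 genes, 20 ranked among the 241 highest gene rows. Next to lrp, gltI, cycA, gdhA and ilvE, the dipeptide binding protein gene dppA had 939 counts against 8 (ratio 84.0, interval 42.4 to 195), and thrL, the threonine operon leader peptide, 367 against 3 (87.5, 29.7 to 426). The cystine binding protein gene fliY had 654 against 7 (66.8, 32.3 to 167), the serine and threonine transporter gene sstT 286 against 3 (68.2, 23.1 to 333), and serA, the first enzyme of serine synthesis, 446 against 5 (63.8, 27.1 to 198). At the low end, ilvC had 56 against 27 (1.48, 0.922 to 2.44) and tsx 23 against 8 (2.06, 0.888 to 5.32), whose intervals include 1. Scaled by the median ratio, their log2 ratios turned from 0.56 to -0.71 and from 1.01 to -0.24. Some members may first have been reported from these libraries. Without 9 members for which that was unsure, a choice made after seeing the data, the list stayed at percentile 100. The percentile was 100 in all 14 settings run for this list, of which those that change the scaling shift the random lists too.

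Amino acid transport genes as a group were also high. Of 45 genes kept, 35 were at least 4-fold higher and none was 4-fold lower, with a median log2 ratio of 3.00, at percentile 99.99. The list shares 12 genes with the reported targets. Without them, 23 of 33 genes were at least 4-fold higher. The median of 2.693 lay at percentile 98.5, barely above the upper limit of 2.690 of the random lists. No alternative setting was run for this shortened list. It also keeps other genes of the targets' operons, such as gltJ and hisQ, so a shift beyond the targets is not settled. Besides gltI, the full list included gltJ (110 against 1), hisQ (38 against 1) and putP, the proline symporter gene (34 against 1). In contrast, gadC (83 against 60) and tdcC (21 against 16) had ratios of 0.990 and 0.939. Of 13 dipeptide and oligopeptide transport genes, 10 were at least 4-fold higher, but their median of 2.31 was at percentile 56.8, within the range of random lists. It was at percentile 99.0 with a listed 1 raised to 3 counts and at 98.4 with a minimum of 50 counts, where 5 genes were left. dppA led that list. oppA, the oligopeptide binding protein gene and a reported target, was abundant in both libraries, with 7415 against 1071 counts and a ratio of 4.95 (4.65 to 5.29).

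Amino acid synthesis genes stood apart in the same direction. Of 76 genes kept, 48 were at least 4-fold higher and 4 at least 4-fold lower, with a median of 2.69 at percentile 99.9. Without the 7 reported targets the median was 2.62, at percentile 98.8, against an upper limit of 2.53 of the random lists. No alternative setting was run for this shortened list, which keeps other genes of the targets' operons. cysJ led the full list, followed by ilvB, gdhA and ilvE. The asparagine synthetase genes asnA and asnB had 2272 against 28 and 371 against 10 counts, and cysK, of cysteine synthesis, 1142 against 32. The 4 lower members were cysN (60 against 209) and cysC (5 against 22) of sulfate activation, argG (23 against 85) and carB (39 against 129).

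**Figure D2:**
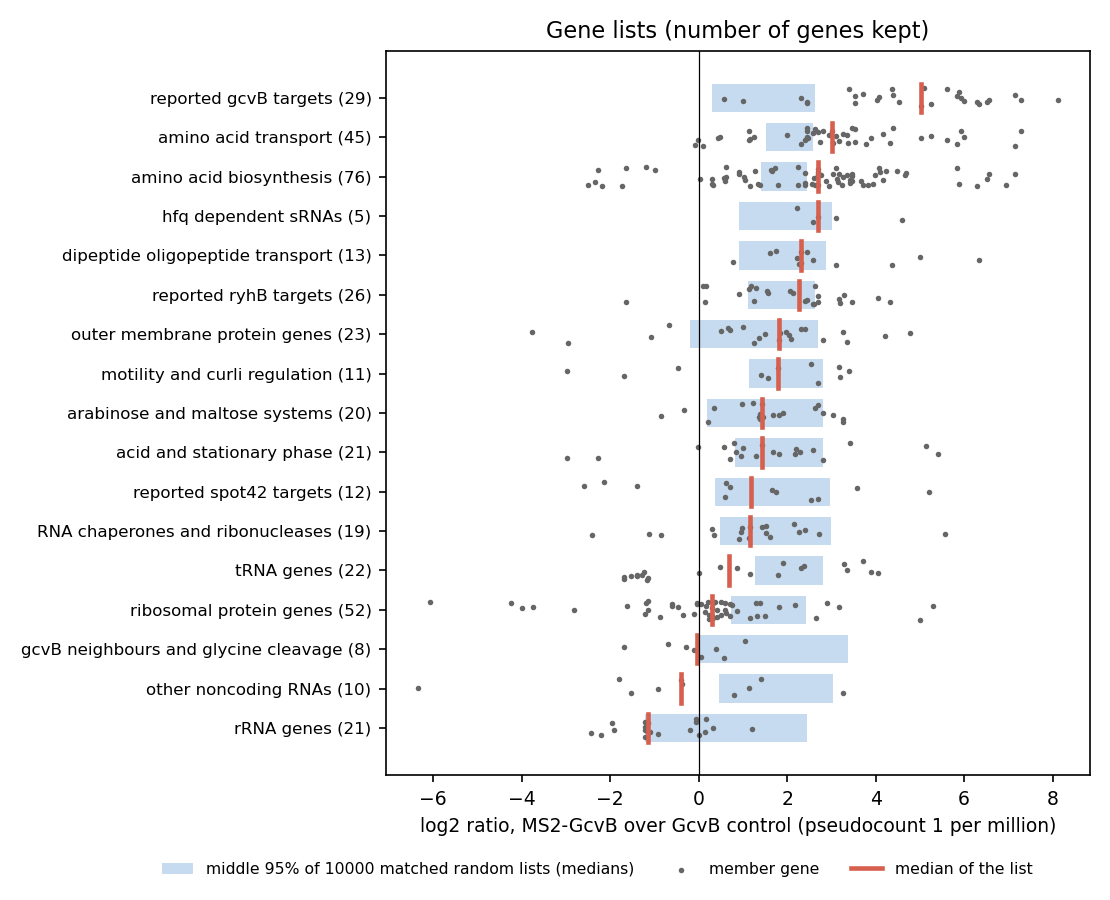
Log2 ratio of MS2-GcvB over control (x axis, pseudocount 1 CPM) for the genes of 17 lists fixed before the data were examined. Points are genes, red bars list medians and blue bands the middle 95% of medians of 10000 random lists matched on level, from 1 library per group. The medians of reported GcvB targets (5.03), amino acid transport (3.00) and amino acid synthesis (2.69) lie right of their bands, and those of ribosomal protein genes (0.31), tRNA genes (0.68), other noncoding RNAs (-0.39) and the gcvB neighbourhood with glycine cleavage (-0.03) lie left of theirs, and the sign of these last 4 medians turned under some settings.

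The medians of the lists of other noncoding RNAs, tRNA genes and rRNA genes lay below the median gene, which 1 of 10, 7 of 22 and 0 of 21 members exceeded. For the other noncoding RNAs the median was -0.39, at percentile 0.30. They included 4.5S RNA (ffs, 4 against 11 counts), 6S RNA (ssrS, 49 against 102), tmRNA (ssrA, 292 against 394) and RNase P RNA (rnpB, 80 against 76), and symR, an antisense RNA, was highest with 18 against 1. Lowest was tff with 92 against 5353, which is in this list but not in the share of noncoding RNA genes above. The median was 0.11 with the authors' number per library and 0.09 without a filter on low counts, and with a minimum of 50 counts the percentile was 9.85. The median of 22 tRNA genes was 0.68 (-0.58 when scaled by the median ratio, and -0.05 with totals without rRNA, tRNA, gcvB and the tff-rpsB-tsf rows), with 7 at least 4-fold higher and none 4-fold lower, and no random list was as low. Some tRNA genes are near-identical copies, which the random lists do not reproduce, so this percentile may be too extreme. glnU was highest with 55 against 2 counts. With a minimum of 50 counts only 3 tRNA genes were left, and the list then lay at percentile 79.4. The 21 rRNA genes had a median of -1.15, at percentile 7.79 (percentile 0.59 without a filter on low counts and 0 with random lists not matched on level), with rrfB highest (114 against 35, a log2 ratio of 1.21 that turned to -0.06 when scaled by the median ratio). In the list of Hfq-dependent sRNAs 5 genes had enough counts, and all 5 were at least 4-fold higher: spf, which encodes Spot 42 (80 against 2), fnrS (221 against 18), mgrR (12 against 1), arcZ (11 against 1) and micA (15 against 2). Their median of 2.69 was at percentile 84.2, and at percentile 98.1 with a listed 1 raised to 3 counts. However, spf, mgrR, arcZ and micA passed the minimum count only through the MS2-GcvB library, which favours high ratios. Without a filter on low counts, the 24 genes of the list had a median of 0.87, at percentile 88.45.

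Ribosomal protein genes stood apart on the low side. Of 52 genes kept, 6 were at least 4-fold higher, 5 at least 4-fold lower and 41 in between, with a median of 0.31, which was 1.71 below the median gene and at percentile 0.16. Its sign turned under 2 scalings. With the median ratio of genes above 1 in both libraries the median was -0.96 and the percentile 3.02, and with totals without rRNA, tRNA, gcvB and the tff-rpsB-tsf rows the median was -0.43. The 5 lower genes were rpsB (433 against 20853), rplC (462 against 6281), rplD (478 against 5427), rpsJ (134 against 1295) and rplW (177 against 900). The highest was rpsT with 76 against 1. Of the 4 lowest gene rows, tff, rpsB and tsf are neighbours. The noncoding RNA gene tff had 92 counts against 5353, a ratio of 0.0123 (0.00990 to 0.0151). rpsB, encoding ribosomal protein S2, had a ratio of 0.0149 (0.0135 to 0.0163), and tsf, encoding elongation factor Ts, one of 0.0508 (0.0415 to 0.0617) with 110 against 1549 counts. deaD, an RNA helicase gene, had 30 against 507 (0.0423, 0.0283 to 0.0612).

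The 8 genes of the gcvB neighbourhood and the glycine cleavage system had a median of -0.03 (-1.29 to 0.49 over the alternatives), at percentile 2.27, and none passed 4-fold. gcvP was highest with 67 against 23 counts, a log2 ratio of 1.05 that turned to -0.22 when scaled by the median ratio. This percentile was between 0.53 and 23.8 over the alternatives, so the list did not stand apart under each of them. The other lists lay within the range of random lists. Reported targets of RyhB, another Hfq-dependent sRNA, had a median of 2.27 over 26 genes (percentile 67.5), led by shiA with 66 against 2. Reported targets of Spot 42 had 1.19 over 12 genes (percentile 21.1, with a median of -1.39 with a minimum of 50 counts and -0.06 when scaled by the median ratio), led by maeA with 173 against 3. RNA chaperone and ribonuclease genes had 1.16 over 19 genes (percentile 13.7, with a median of -0.11 when scaled by the median ratio), led by rppH with 225 against 3. Outer membrane protein genes had 1.81 over 23 genes (percentile 75.7), led by bamD with 281 against 7. Motility and curli genes had 1.79 over 11 genes (percentile 30.2), led by fliZ with 20 against 1. Acid and stationary phase genes had 1.44 over 21 genes (percentile 22.2), led by osmE with 141 against 2. Arabinose and maltose genes had 1.44 over 20 genes (percentile 43.7), led by lamB with 501 against 37.

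Regions between genes were ranked after the data were seen, and the 12 highest and 4 lowest are named. Of 865 regions kept, 513 were at least 4-fold higher and 51 at least 4-fold lower. In 334 the control value was listed as 1, and the filter alone put these past 4-fold. After the region between gcvA and gcvB, the highest was the region between dppA and proK, with 2270 counts against 2 (ratio 812, interval 225 to 6709). The authors' deposited table gives 1156.9 for it. The regions between asnC and asnA (492 against 1), ilvB and ivbL (372 against 1), ybhK and moaA (290 against 1), dcuB and dcuR (258 against 1), gltJ and gltI (400 against 2), trxB and lrp (310 against 2), gltI and insH4 (308 against 2), cysJ and queD (169 against 1), ivbL and istR (169 against 1), and uspA and dtpB (161 against 1) came next. In the RefSeq gene order sroC, an sRNA gene, lies between gltJ and gltI. The 36 regions kept that adjoin a reported target had a median log2 ratio of 4.19, at percentile 100 of matched random regions, and 34 were at least 4-fold higher. The region between ychE and oppA held 14836 counts against 289, a ratio of 36.7 (32.7 to 41.4), whose interval does not overlap that of the oppA gene. The 4 lowest regions were those between tff and rpsB (83 against 4640), rpsB and tsf (253 against 10154), yhfG and ppiA (1 against 23), and rplD and rplC (131 against 1600).

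Along operons that hold a reported target, listed after the data were seen, the ratios differed between genes. thrL had 87.5 (29.7 to 426) and thrA 3.11 (2.23 to 4.41), and fliY had 66.8 and the adjoining dcyD 0.932 (0.615 to 1.42), so these intervals do not overlap. dppA at 84.0 (42.4 to 195) and dppB at 7.87 (1.14 to 339) have intervals that overlap, as do gltI at 166 (76.0 to 453) and gltJ at 78.7 (13.8 to 3136). oppA at 4.95 lay between oppB at 3.43 (1.72 to 7.61) and oppC at 5.49 (1.66 to 28.5), with overlapping intervals. The interval of the target lay above those of all other genes kept in 2 of 11 operons, those of thrL and fliY.

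**Figure D3:**
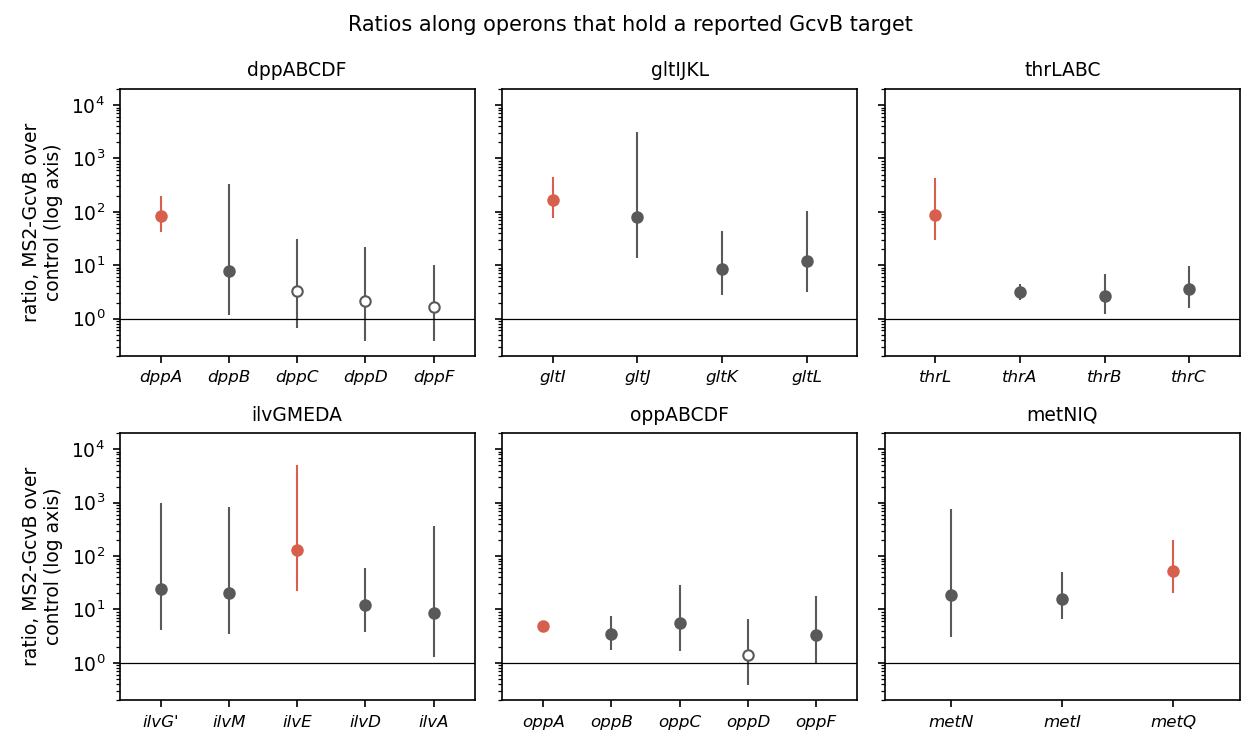
Ratio of CPM, MS2-GcvB over control (logarithmic y axis), for the genes of 6 operons in transcription order. Points are genes with exact 95% counting intervals from 1 library per group, red marks reported targets, open circles genes under 10 counts in both libraries, and the line marks a ratio of 1. In 5 of these 6 operons the reported target has the highest ratio (thrL at 87.5 against 3.11 for thrA, for example), and in oppABCDF it does not.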

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

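The search for sequences complementary to GcvB, with its other window, motif length, gene numbers and minimum count, was not run because no genome sequence was used here. No paired analysis was possible because each group has 1 library, which also leaves no replicate to omit. Alternatives chosen after seeing the data were the authors' number per library, centring on the median gene, the totals without the tff-rpsB-tsf rows, both treatments of the listed 1, the regions in place of genes and the shortened target lists.

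The number of genes at least 4-fold higher was 1221. It was 501 when libraries were scaled by the median ratio of genes above 1 in both, 562 with a pseudocount of 10, 364 of 701 genes with a minimum of 50 counts, 570 at an 8-fold threshold, 185 relative to the median gene and 513 among regions. The number of genes at least 4-fold lower was 114. It was 260 with the median ratio, 75 without scaling, 226 at 2-fold, 34 at 8-fold, 69 with the authors' number per library, 380 relative to the median gene, 186 with totals that leave out rRNA, tRNA, gcvB and the tff-rpsB-tsf rows, and 51 among regions. These scalings moved the median log2 ratio of all genes kept from 2.02 to between 0.82 and 2.47, apart from centring, which sets it to 0. The log2 ratio of gcvB was 7.23. It was 5.95 with the median ratio, 6.99 with totals without rRNA, tRNA and gcvB, 7.71 without scaling, 7.74 with the authors' number, 5.21 relative to the median gene and 6.48 without the tff-rpsB-tsf rows as well.

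The reported targets stayed at percentile 100 in 14 settings, with medians from 3.58 to 5.88, though a change of scaling shifts the random lists too. Amino acid transport stayed between the 99.9th and 100th and amino acid synthesis between the 99.6th and 100th. With a minimum of 50 counts, other noncoding RNAs were at percentile 9.85 with 4 genes, the gcvB neighbourhood at the 23.8th with 4, and tRNA genes turned to the 79.4th with 3, which the fewer genes left may account for. Ribosomal protein genes were at 3.02 and the gcvB neighbourhood at 5.02 under the median ratio. The latter was also at 2.59 without a filter and 3.27 with totals without the tff-rpsB-tsf rows. The cause was not tested. Lists that did not stand apart crossed the middle of the random lists as follows: outer membrane proteins at 34.7 with unmatched random lists, motility and curli at 71.7 without a filter and 53.5 with the listed 1 raised, acid and stationary phase at 57.2 with a minimum of 50, and arabinose and maltose at 58.1 with the median ratio, 60.7 with a pseudocount of 10, 55.0 with a minimum of 50 and 55.0 with the listed 1 raised. The log2 ratios of single named genes and the percentiles of lists that did not stand apart were counted once per alternative. Of these, 387 stayed within the gene's counting interval or on the list's side of the middle and of the limits. Another 58 gene values moved beyond their counting interval and 5 percentiles passed the limits. Intervals of genes with a listed control value of 1 are wide, so staying within them is a weak check. Those that moved include ilvC, tsx, gcvP and rrfB, whose sign turned under the median ratio and relative to the median gene, and for ilvC also with totals without the tff-rpsB-tsf rows.

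As a percent of counts without rRNA, gcvB was at 26.4 and 0.282 in the MS2-GcvB and control libraries, and tRNA at 0.234 and 0.211. The other sRNA and noncoding RNA genes, without tff, were at 0.293 and 0.470. As a percent of the authors' number, these classes were in the same order at 2.17 and 0.0102, 0.0193 and 0.00761, and 0.0241 and 0.0170. In the control, 4093 of 7374 rows are listed at 1, so ratios against them are poorly known. Their counting intervals are wide and take the listed value as 1 read, and with 0 reads a ratio has no finite upper limit. How much of the low counts in the control comes from its depth and how much from its composition was not tested.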

Other observations

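The tests on unequal shares, low control counts, the listed minimum, whole operons, gene order within operons, a pile-up of reads and ribosomal protein genes were chosen after the results they bear on, or values close to them, were seen, as were the uses made here of the scalings, of which the median ratio, the totals without rRNA, tRNA and gcvB, and no scaling were themselves fixed before the data were examined.

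Several further genes were picked after their values were seen, as single genes and not as members of tested groups, in libraries where 50.6% of the genes kept were at least 4-fold higher. raiA, which encodes a ribosome-associated inhibitor, had 7133 counts against 75 (ratio 68.0, interval 54.2 to 86.6), the region between bamD and raiA 3036 against 28, and rmf, the ribosome modulation factor gene, 626 against 7 (64.0, 30.9 to 160). panB had 222 against 4 and panC 96 against 4. The sulfate binding protein gene sbp had 99 against 1, the regulator gene cysB 115 against 2 and cysI 163 against 11, whereas cysD had 37 against 17 (ratio 1.56) and cysN 60 against 209. The restriction genes mcrB and mcrC had 382 against 3 and 189 against 2.

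On the low side, also picked after their values were seen, were the ATP synthase genes atpA (222 against 1895) and atpG (248 against 2478), tolC (42 against 411), treC (300 against 2165) and dps (361 against 2027). The 2 lower members of the list of reported Spot 42 targets were galK (100 against 314) and galT (273 against 1185), while 4 of its 12 genes, maeA, xylF, caiA and yjiA, were at least 4-fold higher, and the list lay within random lists. The count ratio of 16S to 23S rRNA was 1.20 in the MS2-GcvB library and 0.495 in the control.

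Within operons that hold a reported target, the target tended to have the highest ratio. This was so in 9 of 11 operons with at least 2 genes kept, where 4.03 would be expected if the order were random. It was so in 8 by the plain ratio, since brnQ (5.72) lay above proY (6.08) only through the pseudocount, and the counting interval of the target lay above all others in 2, so most single operons do not resolve the order. In all of these operons except metNIQ and ilvGMEDA the target is the first gene, so being a target cannot be told apart from that position. trpE and csgD had too few counts to enter. At these low counts trpC (36 against 1, ratio 25.8) lay above trpE (9 against 2, 3.22), while csgD (7 against 1) was highest in its operon. hisJ and hisQ, and all genes of ilvGMEDA kept except ilvD, had a listed control value of 1. There the order is that of the MS2-GcvB counts, so a random order is no sure baseline where the target is the most abundant gene. fliY and hisJ are among the targets that may first have been reported from these libraries. thrL had a ratio of 87.5 and thrA, thrB and thrC had 3.11, 2.68 and 3.58. fliY had 66.8, and dcyD, yecS and yecC 0.932, 1.07 and 2.33. dppA had 84.0 and dppB 7.87. metQ, the last gene of metNIQ, had 53.7 against 18.6 for metN and 15.9 for metI. ilvE, inside ilvGMEDA, had 127 against 24.3 for ilvG', 20.7 for ilvM and 11.9 for ilvD. The exceptions were oppC above oppA and phoQ above phoP.

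Reported targets lay above random gene lists. Raising control values of 1 to 3 counts left the list at percentile 100, which argues against the listed minimum as the whole cause. The lowest percentile over 4 scalings was also 100, but a scaling shifts the list and the random lists together, so this value does not test it. A higher abundance of whole operons in the MS2-GcvB culture predicts a like rise of all genes of an operon. The target exceeded the median of its operon's other genes by a median of 1.96 on the log2 scale (range -0.05 to 5.89, above 0 in 10 of 11 operons, in brnQ by little). That median is the livK operon (livK 10 against a listed 1, livM 10 against 5). Where control values are a listed 1, a like rise can give such a difference if the target is the most abundant gene. A like rise of all genes kept is argued against for the operons of thrL and fliY, where the target's counting interval lay above all others. thrL encodes a leader peptide, and whether its reads came from transcripts that reach thrA was not examined. The interval of gltI (76.0 to 453) lay above that of gltK (2.71 to 43.6), but overlapped those of gltJ and gltL. The interval of dppA lay above those of dppC, dppD and dppF, and that of hisJ above that of hisM. These lower dpp and his genes had under 10 counts in both libraries. fliY may first have been reported from these libraries. The difference the design names is the MS2 tag on the bait. Local retention of the paired mRNA with the tagged bait may account for the higher ratios of the targets. It stays a hypothesis, because RNA from before the column is not analysed here and each group has 1 library.

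Most genes were higher with MS2-GcvB on the CPM scale, by a median log2 ratio of 2.02. Scaled to totals without rRNA, tRNA, gcvB and the tff-rpsB-tsf rows, which took unequal shares, the median was still 1.35, so these shares account for part of it at most. Among 439 genes with 100 or more counts over both libraries the median was 1.39, and 0.66 with those totals as well. That sum holds the change itself, and 12 of these genes had a control value of 1, so low control counts stay open, alone or together with the shares, as do a difference in background binding between the columns and a general retention of mRNA with the tagged bait, which were not tested.

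The tff, rpsB and tsf rows were far lower with MS2-GcvB. The scaling cannot be the whole cause, since the median of the 5 adjacent rows was -5.56 or lower under 6 scalings. All 5 adjacent rows were at least 4-fold lower, but they were picked because they were low. In the control they held 5353 (tff), 4640, 20853 (rpsB), 10154 and 1549 (tsf) counts. A pile-up of reads inside 1 row thus does not account for all 5, while how reads lay within the rows was not examined. The other 51 ribosomal protein genes had a median log2 ratio of 0.32, which argues against a general drop of their mRNAs as large as that of these rows. A smaller general drop is not argued against. The ribosomal protein list lay 1.71 below the median gene, at percentile 0.16, and the sign of its median turned under 2 scalings. A difference between the 2 cultures or columns, or a competition of the tagged bait for the coat protein with RNAs that bind it, may also explain the rows. Neither was tested, and 1 library per group cannot separate them from an effect of the tag.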
